A study of Mus musculus with 18 samples.

How the data were processed

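Total RNA from 18 samples of 3 primary Eµ-myc lymphomas was labelled by the one-cycle Affymetrix protocol and hybridised to mouse arrays of 45101 probe sets. The authors deposited log2 signal values made with RMA, with Partek named as a further tool, and no version, order or parameter was stated. The deposited values ran from -1.95 to 15.87. Every one of the 45101 probe sets had the same median over the arrays of each of the 3 lymphomas (tolerance 1e-06), so offsets between lymphomas had been removed before deposit, a step that the labels do not state. Of 18 value columns, 17 were used, and 1, the ADR outgrowth of lymphoma 5043, held no values and carries a label saying that it failed quality control. Arrays give no depth, and their number limits the precision.

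Probe sets were named from the platform annotation: 34958 had 1 gene symbol, 932 had several and were left out, and 9211 were not listed, 64 of them control probe sets. Of the 18194 genes, each represented by its probe set with the highest mean over the arrays, 11897 were tested, those with a value of at least 4.86, the median of all values, in at least 3 arrays. Positions are those of the GRCm38.p6 gene table.

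The model had a term for each of the 6 groups and an additive block for lymphoma, because the treatment protocol says that each lymphoma received both treatments. It was fitted with limma 3.58.1 in R 4.3.3, with 9 residual and 2.53 prior degrees of freedom, and tests were adjusted by Benjamini-Hochberg over genes in each comparison at 0.05. The comparisons were ADR+4-OHT 5 d and ADR 5 d against untreated and against each other, big against small outgrowth, small outgrowth against ADR outgrowth, and, as secondary ones, ADR outgrowth and small outgrowth against untreated, big outgrowth against ADR+4-OHT 5 d, and the difference between the small outgrowth minus ADR outgrowth change and the 4-OHT change at 5 days. The pairing of arrays could not be checked on the values: removing the lymphoma medians forces deviations within a lymphoma apart, and the median correlation of group-centred values was -0.117 for arrays of the same lymphoma (40 pairs) and 0.058 for arrays of different lymphomas. An offset common to the arrays of a lymphoma does not enter differences within it.

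Before the data were examined, 24 gene lists with 692 entries were fixed, of which 643 had a named probe set. They cover replication, mitosis, repair, senescence, signalling, stress, metabolism and chromatin, and the markers of B cells and of other cells that the cultures could hold. Lists were tested with camera of limma, two-sided, at a preset correlation of 0.01 and adjusted over the 216 tests of lists and comparisons, and again with a correlation estimated per list. Members were also adjusted over the list alone.

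The genes named were chosen by a rule also fixed before the data were examined. It takes Suv39h1, Bcl2, Myc, Trp53, Cdkn1a and Cdkn2a. For each of the 5 main comparisons it adds the 5 rising and 5 falling genes with the largest change among those that passed with the same sign in every lymphoma, and in each list up to 4 passing members. Where fewer than 2 passed it takes the 2 with the largest change, given as values. For the secondary comparisons it takes 3 rising and 3 falling genes and up to 2 members per list. Genes used to judge the identity of arrays, such as Xist, were chosen after their values were seen.

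Alternatives fixed beforehand were a fit without the block for lymphoma, no filter and a stricter filter at the 60th percentile, the mean over probe sets, every probe set on its own, quantile normalisation, median centring, a variance trend with robust fitting, the compared arrays alone, a gene-by-gene paired test and leaving out each lymphoma. Alternatives added after the data were seen left out 3 or 4 arrays with outlying values, weighted the arrays by quality, or left out each of the 17 arrays in turn. The method was tested on simulated data with the design of these arrays and the spread of each gene, drawn independently between genes: 200 of 11897 genes were changed, and for ADR+4-OHT 5 d against ADR 5 d limma called 6.0% of those changed 1.5-fold, 43.3% of those changed 2-fold and 92.4% of those changed 4-fold, with 2 unchanged genes called. For small outgrowth against ADR outgrowth these shares were 4.5%, 29.9% and 83.3%. The gene-by-gene paired test called 0 of the changed genes of each size in both simulations, so its counts of 0 do not show that no gene changed. The spread of a gene was the same on every simulated array, so outlying arrays were not represented. As signs of RNA quality, the difference between 3′ and 5′ control probe sets ran from 0.345 to 0.796 for Gapdh, from 0.563 to 1.81 for Actb and from 1.18 to 3.36 for Tfrc. For Actb it was lower after 5 days of ADR alone than in untreated cells in lymphomas 4146, 4936 and 5043, by 0.31, 1.09 and 0.24, and higher with 4-OHT than with ADR alone, by 0.43, 0.61 and 0.10, so RNA quality may differ between these groups. Gapdh and Tfrc did not move the same way in all 3 lymphomas in either comparison. For small outgrowth against ADR outgrowth, in 4146 and 4936, Gapdh was higher by 0.07 and 0.23 and Actb by 0.21 and 0.55, and for ADR outgrowth against untreated Gapdh was lower by 0.17 and 0.04 and Actb by 0.07 and 0.39. For small outgrowth against untreated Actb was higher in all 3 lymphomas. For ADR+4-OHT 5 d against untreated, Tfrc differed by 1.17, -0.23 and -0.88 in 4146, 4936 and 5043, and Actb by 0.12, -0.49 and -0.14. For big outgrowth against ADR+4-OHT 5 d, Tfrc differed by -0.26, 1.43 and 1.55, and Actb by -0.01, 0.59 and 0.32. No control moved the same way in all 3 lymphomas in these 2 comparisons, but RNA quality may differ within lymphomas there too. The deposited values carry no detection calls, so 4.86 served also as the mark of a dim value, a choice made after the values were seen.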

Results

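Gene expression was measured with Affymetrix mouse arrays in primary B-cell lymphoma cells of Eµ-myc mice, in which the Myc oncogene is driven in B cells. The lymphomas lacked Suv39h1, an enzyme that methylates histone H3 in heterochromatin. The cells carried Bcl2, a protein that blocks apoptosis, and Suv39h1-ERT2, a fusion protein that 4-hydroxytamoxifen (4-OHT) switches on. Adriamycin (ADR) is a DNA-damaging drug. The 3 lymphomas, numbered 4146, 4936 and 5043, each gave an untreated culture, a culture after 5 days of ADR and a culture after 5 days of ADR with 4-OHT. After 14 more days without the drugs, outgrowth cultures were taken, and those that had received both compounds were sorted by flow cytometry into morphologically big and small cells. The groups were untreated (n = 3), ADR 5 d (n = 3), ADR+4-OHT 5 d (n = 3), ADR outgrowth (n = 2), small outgrowth (n = 3) and big outgrowth (n = 3). The third ADR outgrowth array, of lymphoma 5043, held no values. The number of arrays limited the precision, with a median SE of 0.22 log2 units for a comparison of 3 with 3 arrays. No group received 4-OHT without ADR.

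Suv39h1 and Trp53, the gene of p53, were not analysed here, because no probe set carried either symbol alone. Bcl2 was read by 5 probe sets with mean log2 values from 4.35 to 8.23, and Myc had a mean log2 value of 11.75. Over all comparisons the lowest adjusted p values at gene level were 0.501 for Bcl2, 0.583 for Myc, 0.661 for Cdkn1a, which encodes the cell cycle inhibitor p21, and 0.502 for Cdkn2a, which encodes the tumour suppressors p16 and p19. In the fit of every probe set on its own they were 0.149, 0.662, 0.694 and 0.585. For ADR+4-OHT 5 d against ADR 5 d the SE was 0.767 for Cdkn1a and 1.915 for Cdkn2a, so these values do not show that either gene was unchanged.

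The arrays labelled ADR 5 d of lymphoma 4936, small outgrowth of 5043 and big outgrowth of 5043 stood apart from the other 14. Their scores on the leading principal component were 66.81, 58.47 and 66.32, and the highest score of any other array was 5.94. Xist, the RNA of the inactive X chromosome, lay 5.70, 5.80 and 5.99 log2 units above its median in the same lymphoma on them. Of 20 immunoglobulin variable-region probe sets, 5, 4 and 3 lay at least 2 log2 units from that median on these arrays, and at most 1 did on any other array. Deviations from that median on the same 3 arrays were 9.52, 6.53 and 6.90 for Afp and 7.79, 1.26 and 3.04 for Cdkn2a. For Cdkn1a they were -1.84, -2.48 and -1.07. The array labelled ADR+4-OHT 5 d of lymphoma 4146 had a deviation of -3.49 for Xist. It was also the other array with 1 variable-region probe set off by 2 log2 units, that of Igkv14-111 at -2.76. Its score on the leading component was -9.06. Its identity is therefore in doubt too, and it enters every comparison that uses ADR+4-OHT 5 d. The 3 arrays that stood apart and this array take part in most of the comparisons.

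**Figure D1:**
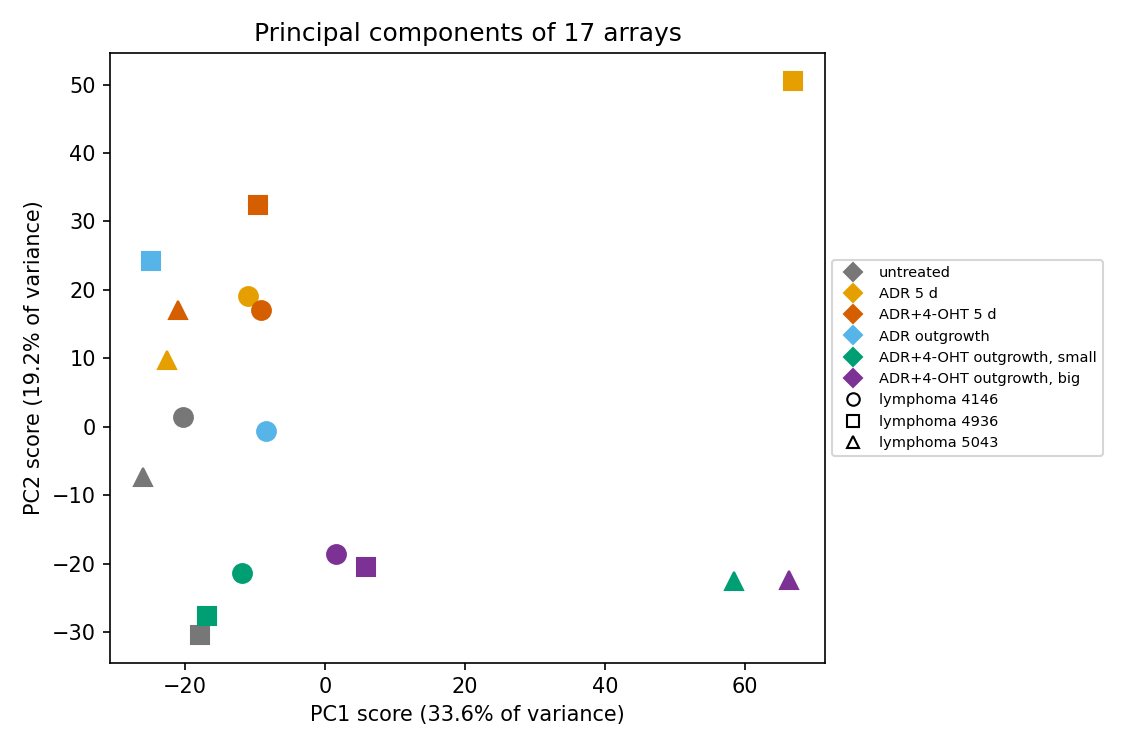
Scores of the 17 arrays on the leading 2 principal components of the log2 values; each point is an array, colours give the group and shapes the lymphoma. The arrays labelled ADR 5 d of 4936 and big and small outgrowth of 5043 score from 58.47 to 66.81 on the horizontal axis, and the other 14 arrays score 5.94 or less.

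After 5 days of ADR with 4-OHT, compared with untreated cells, genes of cell division fell and a small number of secreted and lysosomal proteins rose. This comparison shows the response to ADR and 4-OHT together. The activity of Suv39h1 was not measured, and without a group of 4-OHT alone the fusion protein cannot be separated from 4-OHT itself. Lyz1, a lysozyme of macrophages and Paneth cells, rose by 7.24 log2 units (SE 1.18, adjusted p = 0.0157, n = 3). Mmp13, a collagenase counted among senescence-associated secreted proteins, rose by 6.36 (SE 1.18, adjusted p = 0.0242). Eqtn, known as a protein of the sperm acrosome, rose by 5.18 (SE 0.63, adjusted p = 0.00612), and Cd36, a fatty acid and scavenger receptor, by 4.41 (SE 0.69, adjusted p = 0.0134). Lyz2, the macrophage lysozyme, rose by 5.87 (SE 1.15, adjusted p = 0.0272). The Lyz1 probe set is of a type that can also bind related transcripts, so Lyz1 and Lyz2 may not be 2 separate signals, here or in the counts of macrophage markers below. On GRCm38.p6, Lyz1 lies on chromosome 10 from 117287795 to 117292868, Mmp13 on chromosome 9 from 7272514 to 7283333 and Eqtn on chromosome 4 from 94875697 to 94929953. Among the falls, the linker histone gene H1f4 had -2.89 (SE 0.40, adjusted p = 0.00952), the centromere gene Cenpp -2.27 (SE 0.26, adjusted p = 0.00468) and the kinetochore gene Ska1 -2.20 (SE 0.33, adjusted p = 0.0119). Rasgrp2, an exchange factor for the GTPase Rap, had -2.85 (SE 0.56, adjusted p = 0.0272). Lyz1 and Eqtn on all 3 untreated arrays and H1f4 on all 3 treated arrays lay under 4.86, the median of all values, where a probe set may not be above background. Their exact differences are therefore not measured, and with such values set to 4.86 the rises were at least 6.60 and 3.06, and H1f4 had -1.94 or a larger fall. Lyz2 lay under it on 2 of 3 untreated arrays and Mmp13 on 1.

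Of the 39 mitosis genes tested in this comparison, 16 fell over all genes and 37 fell when adjusted over the list alone, with a median of -1.21. Nuf2, a part of the kinetochore that holds microtubules, fell by 1.95 (SE 0.32, n = 3), the mitotic kinase gene Aurkb by 1.77 (SE 0.33), the spindle motor gene Kif11 by 1.83 (SE 0.42) and the proliferation marker Mki67 by 1.65 (SE 0.37). Of 41 DNA replication genes, 6 fell over all genes and 26 over the list alone, with a median of -0.89. They included Tk1, a thymidine kinase, at -1.85 (SE 0.33), Gins1, a part of the replicative helicase, at -1.77 (SE 0.31), Pola1, a DNA polymerase, at -1.65 (SE 0.25) and the DNA ligase gene Lig1 at -1.63 (SE 0.34). Of 22 genes of homologous recombination and DNA repair, 7 fell over all genes and 17 over the list alone, with a median of -1.01, among them Rad54b (-2.14, SE 0.45), Brip1 (-1.55, SE 0.26) and Fancd2 (-1.51, SE 0.25). The preset-correlation camera test called all 3 lists down, with adjusted p values of 1.39e-23, 1.84e-16 and 2.2e-13. The adjusted p = 0.5, 0.565 and 0.486 with an estimated correlation, so none of the 3 calls held. The mitosis medians were -0.18 in lymphoma 4146, -1.36 in 4936 and -2.01 in 5043.

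Suv39h2, the gene of the sister enzyme of Suv39h1, fell by 1.20 (SE 0.25, adjusted p = 0.0303, n = 3), and Cbx5, the gene of the heterochromatin protein HP1 alpha, by 0.79 (SE 0.17, adjusted p = 0.0356). They were the 2 of 26 heterochromatin and chromatin-modifier genes that fell over all genes, and 5 fell over the list alone. Cbx5 and Rbl1, a retinoblastoma-related gene that fell by 1.49 (SE 0.29), were also the 2 of 17 genes of the list of CDK inhibitors and senescence regulators that fell over all genes, and 3 fell over the list alone. The median of that list was -0.04 and its adjusted p was 0.238. Of 33 p53 target genes, Ddb2, which recognises damaged DNA, was the 1 that passed, at -1.67 (SE 0.39), and the list had a median of 0.38 with an adjusted p of 0.0806. Asns and Psat1, enzymes of amino acid synthesis that the transcription factor ATF4 controls, fell by 1.27 (SE 0.28) and 1.22 (SE 0.28). They were 2 of 26 genes of the unfolded protein and integrated stress response, a list with 2 rising and 3 falling over the list alone and an adjusted p of 0.235.

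Lysosome genes lay higher after ADR with 4-OHT than in untreated cells, with a median of 0.69, and 2 of 36 rose over all genes and 10 over the list alone. Tpp1, a lysosomal peptidase, rose by 1.41 (SE 0.31, n = 3) and the lysosomal membrane protein gene Lamp1 by 1.24 (SE 0.24). Of 35 interferon response genes, 2 rose over all genes and 3 over the list alone, with a median of 0.61. They included the antiviral gene Rsad2 (2.09, SE 0.36) and Ifi35 (0.98, SE 0.24). Of 31 senescence-associated secretory genes, Mmp13 was the 1 that rose over all genes and 7 rose over the list alone. The chemokine gene Ccl3, at 4.87 (SE 1.18, adjusted p = 0.0509), was among the 7. None of 26 NF-kB target genes passed over all genes and 5 rose over the list alone, with a list median of 0.48. Camera called these 4 lists and the apoptosis list (median 0.32, 0 of 23 rising over all genes and 1 over the list alone) up and the heterochromatin list down. With an estimated correlation the adjusted p = 0.572 for lysosome, 0.572 for interferon, 0.5 for secretory, 0.624 for NF-kB, 0.445 for apoptosis and 0.5 for heterochromatin genes. Markers of other cells moved with these groups: 2 of 17 macrophage markers, the lysozyme genes, rose over all genes and 3 over the list alone, with a list median of 1.54 (camera adjusted p = 4.46e-06, adjusted p = 0.565 with an estimated correlation). The fibroblast list had a median of 0.40 with 0 of 16 passing over all genes or over the list alone (camera adjusted p = 0.0364, adjusted p = 0.787 with an estimated correlation), the median was below 0 in 1 of 3 lymphomas, and the call ended without lymphoma 4936 (adjusted p = 0.281), with array weights (0.0879) or with the mean over probe sets (0.0672). The heterochromatin call ended without lymphoma 5043 (adjusted p = 0.0924).

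**Figure D2:**
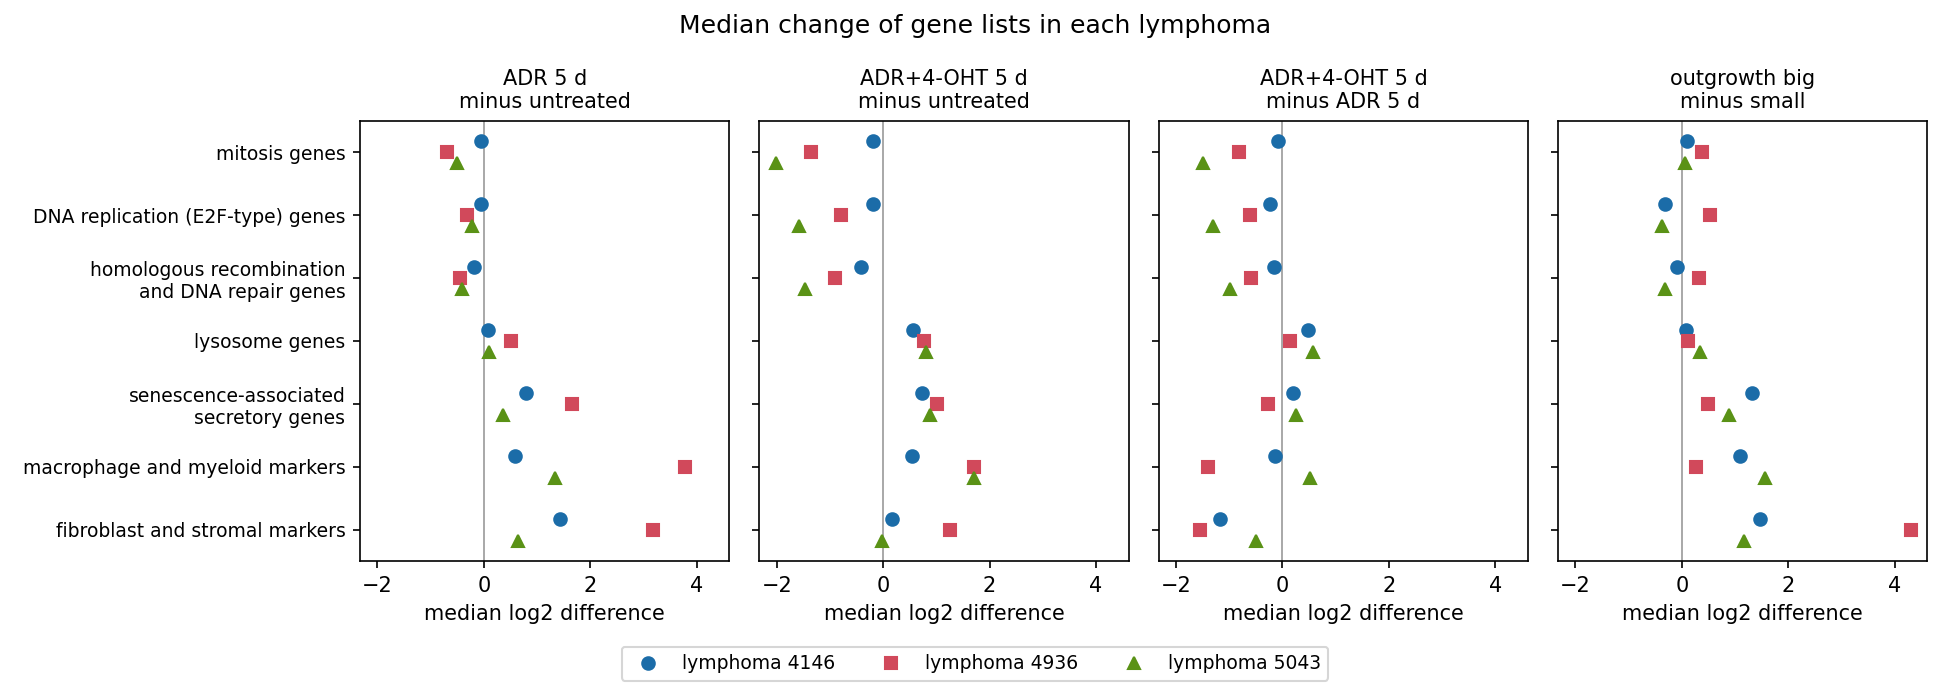
Median log2 difference of 7 gene lists in each of the 3 lymphomas, for 4 comparisons; each point is the median over the tested genes of a list in 1 lymphoma. For ADR+4-OHT 5 d minus untreated the mitosis medians are -0.18, -1.36 and -2.01, and for big minus small outgrowth the fibroblast medians are 1.48, 4.30 and 1.17.

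Over all 11897 genes, 350 passed in limma for ADR+4-OHT 5 d against untreated, 106 rising and 244 falling, and all 350 had the same sign in all 3 lymphomas, as did 42% of all tested genes. Of these, 49 rose and 144 fell by at least 2-fold, and 2287 genes had an unadjusted p under 0.05. The count was 0 without lymphoma 4146, 6 without 4936, 0 without 5043, 0 in a fit of the compared arrays alone, 0 by a gene-by-gene paired test, 212 with the mean over a gene's probe sets, 623 without the block for lymphoma, 793 without the 3 arrays that stood apart and ADR+4-OHT 5 d of 4146, and 1304 with array weights. Without the 3 arrays alone it was 470, of which 294 were among the 350. The paired test called 0 simulated changes even at 4-fold, so its 0 decides nothing here. Leaving out 1 array gave 14 (untreated 4936, or ADR+4-OHT 5 d of 5043), 17 (untreated 5043), 24 (ADR+4-OHT 5 d of 4936), 129 (untreated 4146), 199 (big 4146), 225 (small 4146), 231 (ADR 5 d of 4146) and 545 (ADR+4-OHT 5 d of 4146).

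**Figure D3:**
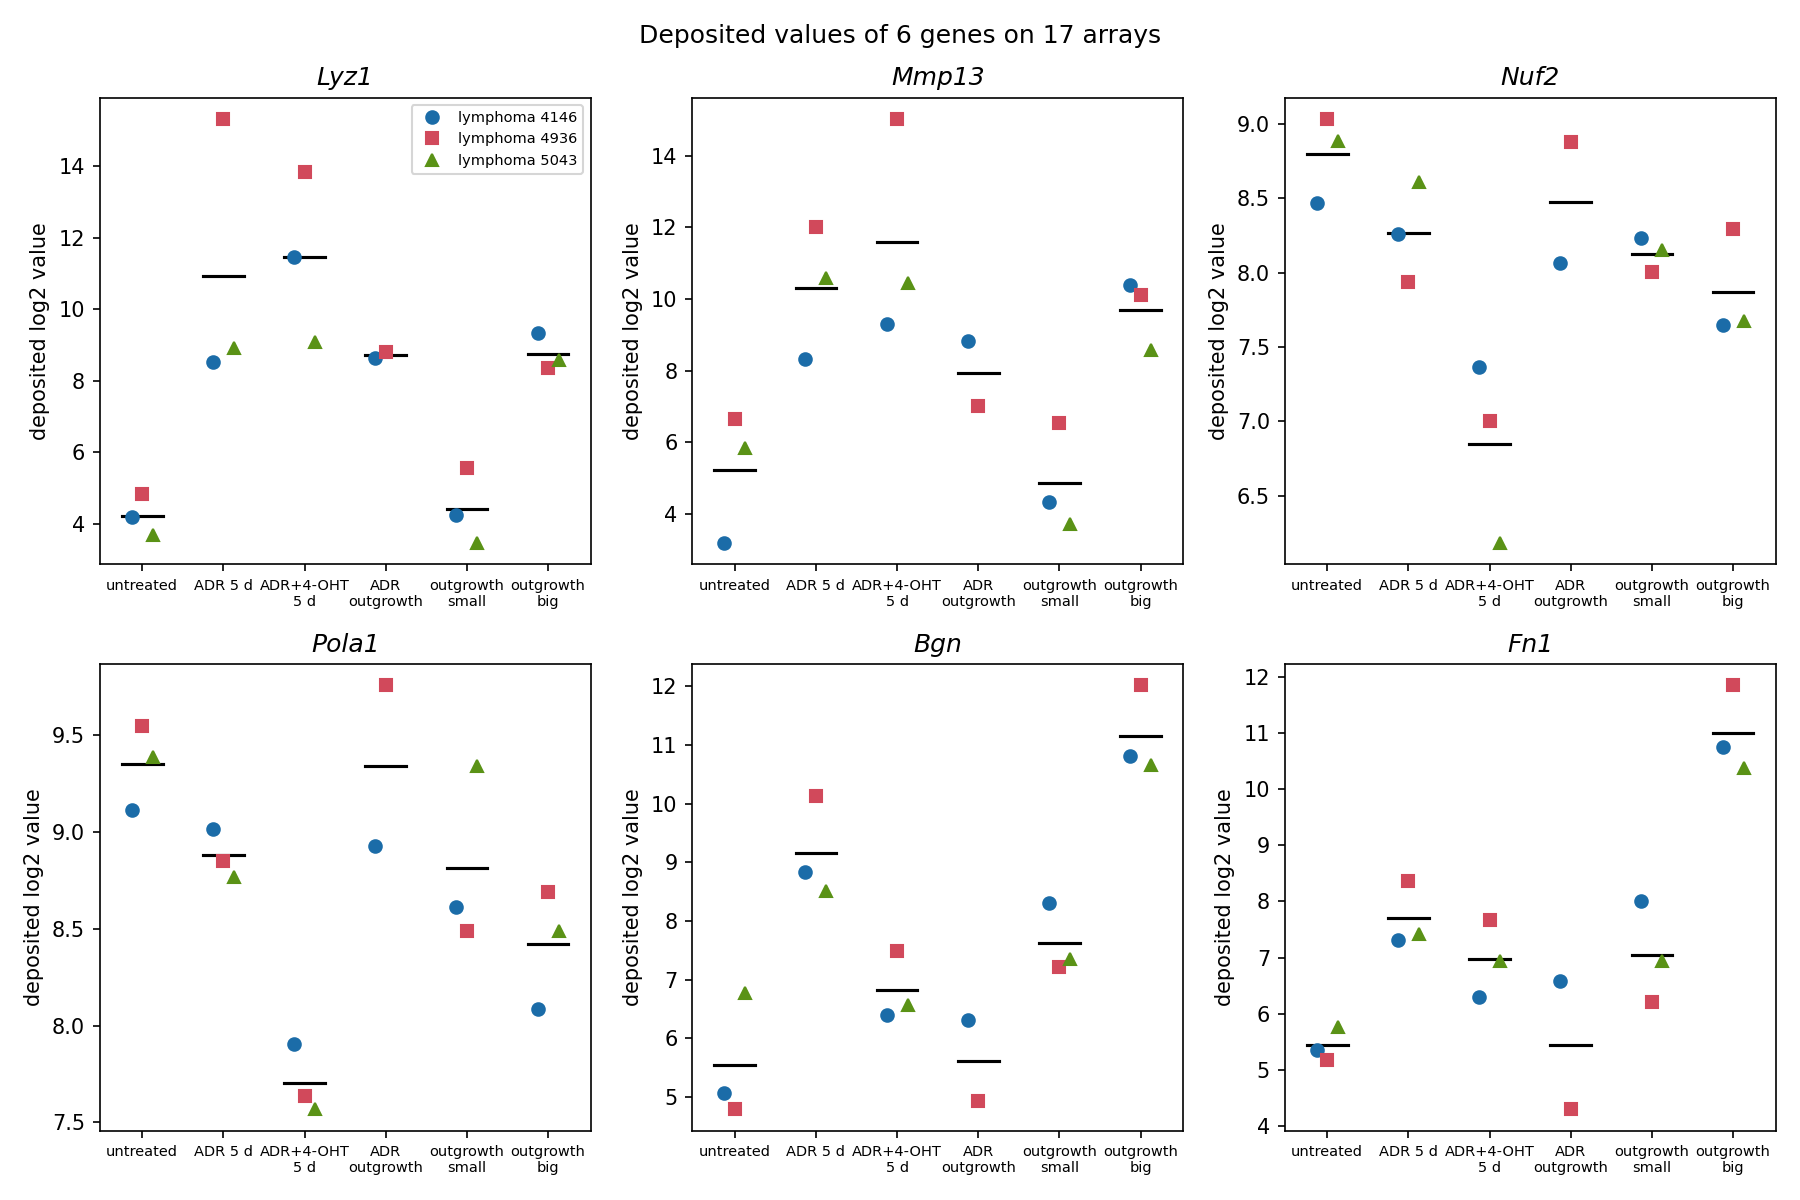
Deposited log2 values of Lyz1, Mmp13, Nuf2, Pola1, Bgn and Fn1 on the 17 arrays by group; each point is an array, shapes and colours give the lymphoma and horizontal bars the group mean. Nuf2 falls by 1.95 and Mmp13 rises by 6.36 log2 units from untreated to ADR+4-OHT 5 d.

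After 5 days of ADR alone, without 4-OHT to switch on the fusion protein, markers of macrophages and fibroblasts and secretory genes lay higher than in untreated cells. Lyz1 had a difference of 6.68 (SE 1.18, adjusted p = 0.208, n = 3) and Lyz2 of 5.66 (SE 1.15, adjusted p = 0.239). The untreated Lyz1 values all lay under 4.86, so its rise is given as at least 6.05, and Lyz2 lay under it on 2 of 3 untreated arrays. Both passed when adjusted over the list alone, as 2 of the 5 of 17 macrophage markers that rose there. Of 16 fibroblast markers 10 rose over the list alone, among them the collagen gene Col1a2 (3.86, SE 0.77) and Bgn, the gene of the matrix proteoglycan biglycan (3.62, SE 0.65). Mmp13, at 5.08 (SE 1.18), was 1 of the 4 of 31 secretory genes that rose over the list alone. The list medians were 1.95 for macrophage, 1.96 for fibroblast and 1.07 for secretory genes. In lymphomas 4146, 4936 and 5043 the macrophage medians were 0.59, 3.78 and 1.33, the fibroblast medians 1.44, 3.18 and 0.64 and the secretory medians 0.79, 1.67 and 0.36, and the Lyz1 values after ADR were 8.52, 15.31 and 8.90. The highest of each came from 4936, where the array labelled ADR 5 d stood apart. The difference between 3′ and 5′ Actb control probe sets, a sign of RNA quality, was lower after ADR than in untreated cells in all 3 lymphomas.

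Mitosis genes had a median of -0.43 after ADR alone and genes of homologous recombination and repair -0.38, with no member passing over all genes or over the list alone. Mki67 had -1.17 (SE 0.37, adjusted p = 0.335, n = 3) and Rad54b -1.32 (SE 0.45, adjusted p = 0.353). Trib3 and Chac1, stress response genes, had -1.91 (SE 0.68) and -1.56 (SE 0.64). In their list, 3 of 26 genes rose and 2 fell over the list alone, and the list adjusted p was 0.706. Interferon genes had a median of 0.40, NF-kB targets 0.28, ribosome biogenesis genes 0.26, DNA replication genes -0.21 and glycolysis genes -0.27, with 0 members passing over all genes or the list alone in these 5 lists. Camera called 10 lists, those of this paragraph except the stress list and those of the macrophage, fibroblast and secretory genes. The adjusted p lay between 0.5 and 0.875 with an estimated correlation. The replication call ended without lymphoma 4936 (adjusted p = 0.0509), 5043 (0.168) or the 3 arrays that stood apart (0.422), and the NF-kB call without 4936 (0.184), without those 3 arrays (0.532) or with array weights (0.116). Without those arrays the macrophage median was 0.94.

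For ADR 5 d against untreated limma called 0 genes, 1348 had an unadjusted p under 0.05, and the gene-by-gene paired test called 0. The count was 1 without the block for lymphoma, 10 with array weights, 3 without ADR outgrowth of 4146 or of 4936, and 1 without ADR 5 d of 5043.

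Adding 4-OHT to 5 days of ADR asks what enabling Suv39h1 adds, but cannot separate the fusion protein from 4-OHT itself. With 4-OHT, genes of mitosis, replication and repair lay lower and lysosome genes higher than with ADR alone. No gene passed over all genes. When adjusted over the list alone, 21 of 39 mitosis genes fell, with a list median of -0.80, and 16 of 41 replication genes, with a median of -0.70. Nuf2 had -1.42 (SE 0.32, adjusted p = 0.181 over all genes, n = 3), Aurkb -1.11 (SE 0.33, 0.237), Tk1 -1.46 (SE 0.33, 0.183) and Pola1 -1.18 (SE 0.25, 0.165), and these 4 passed over their lists alone. Of 22 repair genes 6 fell over the list alone, with a median of -0.67, including the nuclease gene Exo1 (-1.44, SE 0.45) and Fancb, of the Fanconi anaemia complex (-1.12, SE 0.31). The camera test called the 3 lists down (adjusted p = 1.12e-15, 1.32e-14 and 8.49e-08), and the adjusted p = 0.565, 0.572 and 0.5 with an estimated correlation. The mitosis medians were -0.09 in lymphoma 4146, -0.81 in 4936 and -1.49 in 5043.

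Lysosome genes had a median of 0.34 for ADR with 4-OHT against ADR alone, and 1 of 36 rose over the list alone. Tpp1 had 0.84 (SE 0.31, adjusted p = 0.309, n = 3) and Sqstm1, an autophagy receptor, 0.86 (SE 0.38, 0.377). Interferon genes had a median of 0.29, with Rsad2 at 1.46 (SE 0.36, 0.193), and apoptosis genes a median of 0.23, with Bcl2l11, a death-promoting relative of Bcl2, at 0.98 (SE 0.30, 0.246). Glycolysis genes had a median of 0.31, turning to -0.05 without lymphoma 4936, and ribosome biogenesis genes -0.24. The interferon median was below 0 in 1 of 3 lymphomas and the glycolysis median in 2. The difference between 3′ and 5′ Actb control probe sets was higher with 4-OHT than with ADR alone in all 3. No member of these 4 lists passed over all genes or over the list alone. Of 17 senescence regulators 2 fell when adjusted over the list alone, including the chromatin protein gene Hmga2 (-1.44, SE 0.37). Fibroblast markers had a median of -1.24, 5 of 16 fell over the list alone, and Col1a2 had -2.94 (SE 0.77) and Bgn -2.35 (SE 0.65). Suv39h2 had -0.95 (SE 0.25, adjusted p = 0.22) and the list of 26 heterochromatin genes a median of -0.18, with an adjusted p of 0.185.

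Camera called 9 lists for ADR with 4-OHT against ADR alone, those of the repair, mitosis, replication, lysosome, interferon, apoptosis, glycolysis, ribosome biogenesis and fibroblast genes. The adjusted p lay between 0.445 and 0.875 with an estimated correlation. The calls ended for interferon genes without lymphoma 4146 (adjusted p = 0.347) or 5043 (0.0837), for ribosome biogenesis without 4146 (0.459), for glycolysis without 4936 (0.934) or the 3 arrays that stood apart (0.346), and for fibroblast markers without those 3 and ADR+4-OHT 5 d of 4146 (0.0803). The glycolysis call ended also without the block (0.0512) and the ribosome biogenesis call with quantile normalisation (0.0805) or without the 4 arrays (0.0606). Among all genes 0 passed in limma, 1490 had an unadjusted p under 0.05, and the gene-by-gene paired test called 0. The count was 13 without the block for lymphoma, 1 with the mean over a gene's probe sets, 1 with every probe set on its own, 523 with array weights and 19 without ADR+4-OHT 5 d of lymphoma 4146. In data simulated with the spread of these arrays, limma called 29 of 67 genes changed 2-fold and 61 of 66 changed 4-fold, and the paired test 0 of either. The simulation held no outlying arrays, so these shares do not show that large changes were absent. Col1a2 and Bgn, at -2.94 and -2.35, did not pass over all genes (adjusted p = 0.22 and 0.221).

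The big outgrowth cells, compared with the small cells of the same cultures, had higher levels of fibroblast markers and of secretory, NF-kB and glycolysis genes. Of 16 fibroblast markers 14 rose when adjusted over the list alone, with a list median of 2.37. Fn1, the gene of fibronectin, had 3.94 (SE 0.64, adjusted p = 0.0654 over all genes, n = 3) and the calcium-binding protein gene S100a6 3.92 (SE 1.55, 0.392). The stem cell list held Klf4, a pluripotency factor, at 2.94 (SE 0.43, 0.0654) and the progenitor and stromal surface marker Cd34 at 2.29 (SE 0.56, 0.163). These were the 2 of 16 that rose over the list alone, and the list itself had a median of 0.07 and an adjusted p of 0.222. Of 31 secretory genes 3 rose over the list alone, with a median of 1.03, including Mmp13 (4.82, SE 1.18) and Igfbp6, which binds insulin-like growth factors (2.91, SE 0.62). Klf4 and Cd34 lay under 4.86 on all 3 small arrays, and the rise of Klf4 was at least 2.01 against that value. Cd34 lay under it also on 1 of 3 big arrays, and its difference was 1.05 with such values set to 4.86. Mmp13 and Igfbp6 lay under it on 2 of 3 small arrays, and Igfbp6 had 2.71 with those set to it.

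Of 18 glycolysis genes 4 rose over the list alone in big against small cells, with a median of 0.39, among them the enolase gene Eno2 (2.36, SE 0.55, n = 3) and the glucose transporter gene Slc2a1 (1.70, SE 0.45). NF-kB targets had a median of 0.60, macrophage markers 1.03, lysosome genes 0.21, mitosis genes 0.21 and ribosome biogenesis genes -0.28, with no member passing over all genes or over the list alone. Lyz1 had 4.34 (SE 1.18, adjusted p = 0.199), with 2 of 3 small arrays under 4.86 and a difference of 3.66 with those set to it. Eno2 and Fosl1 lay under it on all 3 small arrays, with rises of at least 1.79 and 0.58. The nucleolar genes Ddx21 and Ncl had -0.85 (SE 0.25) and -0.77 (SE 0.26). The B cell list had a median of -0.10 (adjusted p = 0.903). Of 21 Wnt pathway genes, Fosl1, an AP-1 factor, was the 1 that rose over the list alone (1.20, SE 0.29), with a list median of -0.10 against a test direction of up (adjusted p = 0.99). Of 26 stress response genes 1 rose and 3 fell over the list alone (list adjusted p = 0.907).

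Camera called 8 lists for big against small cells, those of the fibroblast, secretory, glycolysis, NF-kB, macrophage, lysosome, mitosis and ribosome biogenesis genes. The adjusted p lay between 0.445 and 0.875 with an estimated correlation. The lysosome call ended without lymphoma 5043 (adjusted p = 0.0967) and the mitosis call without 4936 (0.39). Both arrays of lymphoma 5043 in this comparison stood apart, and without the 3 arrays that did the fibroblast median was 2.96 and the macrophage median 0.68. Among all genes limma found 0, 1243 had an unadjusted p under 0.05, and the gene-by-gene paired test called 0. The count was 30 without the block for lymphoma, 66 genes with every probe set on its own, 61 with array weights, 3 and 2 without the 3 or 4 arrays with outlying values, 1 without lymphoma 5043, 25 without big 5043 and 1 without big 4146.

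The big outgrowth cells, compared with the cultures after 5 days of ADR with 4-OHT, had higher levels of mitosis genes and fibroblast markers, and 2 interferon genes fell. Of 39 mitosis genes 15 rose over all genes and 35 over the list alone, with a median of 1.14. The 3 arrays of the 5-day cultures are also those compared with untreated cells above, so this rise and that fall of mitosis genes are not independent. Kif11 rose by 1.82 (SE 0.42, adjusted p = 0.0405, n = 3) and Anln, which shapes the cleavage furrow, by 1.76 (SE 0.31, adjusted p = 0.0237). Of 16 fibroblast markers 8 rose over all genes and 12 over the list alone, with a median of 2.20, including Bgn (4.34, SE 0.65) and Fn1 (4.02, SE 0.64). Big cells were not tested against untreated cells. The mean of Kif11 was 9.79 in big, 7.97 in 5-day and 9.81 in untreated cells, and that of Bgn was 11.16, 6.81 and 5.54. Lgals3, the gene of galectin-3, had the largest rise by the rule for named genes, 4.96 (SE 0.82, adjusted p = 0.022), followed by Bgn and by the matrix gene Efemp1 at 4.03 (SE 0.80). Efemp1 lay under 4.86 on 2 of 3 arrays of the 5-day culture, with a difference of 3.45 when those were set to it.

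Rsad2 and Parp9 were the 2 of 35 interferon genes that fell over all genes from the 5-day culture to the big cells, by 1.96 (SE 0.36, n = 3) and 1.21 (SE 0.23), and 3 fell over the list alone, with a list median of -0.51. Hsp90b1, a chaperone of the endoplasmic reticulum, and the stress factor Atf4 rose by 0.78 (SE 0.15) and 0.75 (SE 0.19), and 7 of 26 stress response genes rose over the list alone, with a median of 0.45. Klf4 (2.69, SE 0.43) and Cd34 (2.22, SE 0.56) rose, from values under 4.86 on all 3 arrays of the 5-day culture. The rise of Klf4 was at least 2.01. Cd34 lay under 4.86 also on 1 of 3 big arrays, and its difference was 1.05 with such values set to 4.86. Igfbp6 (3.13, SE 0.62) and Timp2, an inhibitor of metalloproteinases (2.37, SE 0.59), rose among 31 secretory genes. Igfbp6 lay under 4.86 on 2 of 3 arrays of the 5-day culture, with 2.72 when those were set to it. Of 16 stem cell genes 2 rose and 2 fell over the list alone, and the medians of the stem cell and secretory lists were -0.15 and 0.00. Rfc4, a clamp loader of replication, rose by 1.27 (SE 0.31) as 1 of 41 replication genes, none of which passed over the list alone. Eqtn had -3.42 (SE 0.63), Pik3r3, a regulator of PI3 kinase, -2.50 (SE 0.50), the caspase activator gene Apaf1 -1.23 (SE 0.26), the lysosomal enzyme gene Gusb -1.20 (SE 0.27) and Polr1a, of RNA polymerase I, -1.05 (SE 0.24), and all of these fell over all genes. Eqtn lay under 4.86 on 2 of 3 big arrays, with -2.91 when those were set to it. The TGF-beta target list had a median of 0.91 (adjusted p = 0.104), with 1 of 11 rising over all genes, the TGF-beta decoy receptor gene Bambi (1.40, SE 0.29), and 2 rising and 1 falling over the list alone.

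Camera called 7 lists for the big cells against the 5-day culture: mitosis, fibroblast, stress response, replication (median 0.18) and repair genes (0.36) up and interferon and ribosome biogenesis genes (-0.53) down. In lymphomas 4146, 4936 and 5043 the mitosis medians were 0.29, 1.29 and 1.79, the replication medians -0.53, 0.49 and 0.72 and the repair medians -0.08, 0.66 and 0.72, so replication and repair went the other way in 4146. The adjusted p lay between 0.5 and 0.875 with an estimated correlation, and the replication call ended without lymphoma 4936 (adjusted p = 0.234) or 5043 (0.641). Over all genes limma called 478, 238 rising and 240 falling, of which 158 and 97 by at least 2-fold, and 2782 had an unadjusted p under 0.05. All 478 had the same sign in all 3 lymphomas, as did 46.4% of all tested genes. The count was 0 without lymphoma 4146, 133 without 4936, 2 without 5043, 0 in a fit of the compared arrays alone, 4 by the gene-by-gene paired test, 920 without the block and 1992 with array weights. It was 46 without the 3 arrays that stood apart, 39 of them among the 478, with 0 mitosis and 7 fibroblast genes called, and 42 without 4 arrays. Leaving out 1 array gave 0 (ADR+4-OHT 5 d of 4936 or 5043, or big 4936), 63 (big 4146), 66 (big 5043), 192 (ADR 5 d of 4146), 242 (small 4146), 298 (ADR 5 d of 5043), 760 (untreated 4936), 803 (ADR outgrowth of 4146) and 804 (ADR outgrowth of 4936).

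The small outgrowth cells after ADR with 4-OHT, compared with the outgrowth after ADR alone, had lower levels of replication, repair, interferon and glycolysis genes and higher levels of fibroblast markers and stress response genes. The small cells were sorted by size and the labels name no sort for the ADR outgrowth, so this comparison does not separate 4-OHT from the sort. The differences between 3′ and 5′ control probe sets of Gapdh and Actb were higher in the small cells in both lymphomas with an ADR outgrowth array. Replication genes had a median of -0.69, with the origin-licensing gene Cdc6 at -1.20 (SE 0.39, adjusted p = 0.281, n = 3 and 2), and repair genes a median of -0.43. Interferon genes had -0.59, turning to 0.22 without lymphoma 4146, and glycolysis genes -0.41, with Hk2, a hexokinase gene, at -1.20 (SE 0.32, 0.243). Heterochromatin genes had a median of -0.28, with Uhrf1, which guides DNA methylation, at -1.13 (SE 0.42, 0.306). No member of these 5 lists passed over all genes or the list alone. Of 26 stress response genes 4 rose over the list alone (median 0.28), and of 36 lysosome genes 2 (median 0.15, turning to -0.18 without lymphoma 4936), including the cathepsin gene Ctsh (1.07, SE 0.28). Pou2af1, a B cell coactivator, was the 1 of 25 B cell genes that rose over the list alone (SE 0.37, adjusted p = 0.243 over all genes), and the list had a median of 0.48 with an adjusted p of 0.0776. Fibroblast markers had a median of 0.74 with 0 of 16 passing, and Bgn 2.05 (SE 0.74, 0.305), the array labelled small outgrowth of 5043 being 1 of the 3 that stood apart.

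Camera called 10 lists for the small cells against the ADR outgrowth: the 8 other than the B cell list in that account, and the Wnt (median 0.21) and plasma cell (0.43) lists. The adjusted p lay between 0.486 and 0.823 with an estimated correlation. The calls that survived leaving out any lymphoma were those of the fibroblast list alone; without 4936 the replication (adjusted p = 0.18), repair (0.0947), heterochromatin (0.189), lysosome (0.415) and stress (0.0954) calls ended, without 4146 the interferon (0.0963), glycolysis (0.489), Wnt (0.229) and plasma cell (0.0969) calls, and without 5043 the stress (0.234), Wnt (0.0712) and plasma cell (0.112) calls. The stress (0.274), Wnt (0.0775) and plasma cell (0.0629) calls also ended without the 3 arrays that stood apart, the glycolysis call with array weights (0.0624), the lysosome (0.0984) and plasma cell (0.0643) calls without a filter, and the lysosome call without 4 arrays (0.0503). No gene passed in limma (0), 1598 had an unadjusted p under 0.05, the gene-by-gene paired test called 0, and 1 gene passed without untreated 4146.

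Lists that camera called in none of the 5 main comparisons were those of the p53 targets, the CDK inhibitors and senescence regulators, the stem cell, TGF-beta, antigen presentation, B cell, T cell and erythroid genes. For ADR with 4-OHT against ADR alone their medians were 0.28 for p53 targets, with Ephx1, an epoxide hydrolase gene, at 1.60 (SE 0.71, adjusted p = 0.383, n = 3), -0.05 for the senescence regulators, 0.12 for stem cell genes with a mean of -0.10 and a test direction of down, -0.31 for TGF-beta targets, 0.06 for antigen presentation genes, 0.15 for B cell genes with a mean of -0.02, -0.07 for T cell markers with a test direction of up, and 0.10 for Epor, the 1 erythroid gene tested. Their adjusted p values were 0.0838, 0.517, 0.992, 0.481, 0.547, 0.534, 0.788 and 0.731. Across genes, the log2 changes for 4-OHT at 5 days and for big against small cells had a Pearson correlation of 0.05 and a Spearman correlation of 0.24. Genes are not independent replicates, no p was computed, the Pearson value was 0.30 without lymphoma 4936 and -0.10 without 5043, and 0 calls in either comparison left no overlap to count.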

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

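The tests of the 3 patterns weighed here were all chosen after the results were seen; the interaction was planned.

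For 7 gene lists, the small outgrowth minus ADR outgrowth change differed from the 4-OHT change at 5 days in its own camera test, and with an estimated correlation the adjusted p lay between 0.445 and 0.792. The small cells were sorted by size and the ADR outgrowth has no sort in its labels, so the design does not separate 4-OHT from the sort, and lymphoma 5043 has no ADR outgrowth array. The medians of this difference were 0.78 for mitosis genes, 2.06 for fibroblast markers and 0.39 for unfolded protein and stress response genes. They were -0.37 for NF-kB targets, -0.82 for interferon genes, -0.30 for apoptosis genes and -0.47 for glycolysis genes. Of the members, 5 fibroblast and 6 stress genes rose and 1 glycolysis gene fell when adjusted over the list alone. The limma count over all genes was 0, 1129 had an unadjusted p under 0.05, the gene-by-gene paired test called 0, and 1 passed without the block and 2 without ADR outgrowth of 4936. Without lymphoma 4146 the NF-kB and interferon medians were 0.61 and 0.09, and the apoptosis call ended (adjusted p = 0.489), as it did with the mean over probe sets (0.109). The mitosis medians were 0.05 in 4146 and 0.43 in 4936. The mitosis call ended without 5043 (median 0.34, adjusted p = 0.0742), as did that of NF-kB targets (0.0606), and the stress call without 4936 (0.0869) or the 3 arrays that stood apart (0.0619; 0.183 without 4).

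The arrays labelled ADR 5 d of lymphoma 4936 and big and small outgrowth of 5043 stood apart from their own lymphomas and resembled each other, with correlations of their deviations across genes of 0.57, 0.50 and 0.81. Macrophages in the cultures as the whole cause are argued against by at least 2 of 20 immunoglobulin variable-region probe sets that lay higher by 2 log2 units or more on each of the 3 arrays, and 0 on any other array. A share of macrophages stays open on ADR 5 d of 4936, where their list lay at 3.03 from the lymphoma median. On small outgrowth of 5043 the list lay at -0.98, with Lyz1 at -5.12 and Lyz2 at -5.24, which gives no sign of such a share. On big outgrowth of 5043 the list lay at 0.13, with Lyz1 and Lyz2 at 0, Csf1r at 1.05 and Tyrobp at 1.54. A deviation of 0 means that this array gave the median of its lymphoma. Its Lyz1 value was 8.58, against 3.67 in untreated cells, 8.90 after ADR and 9.09 after ADR with 4-OHT. The list lay at -1.14 in untreated cells of 5043. A share of macrophages therefore stays open on the big array too. An effect of the treatment or cell fraction in these lymphomas stays open too: the other arrays of the same groups had scores of at most 5.94 on the leading component, but the 3 arrays were picked by that score, so it decides nothing. A wrong label or RNA of another lymphoma stays open, since at least 3 of 20 immunoglobulin variable-region probe sets were off by 2 log2 units or more on each of the 3 arrays and at most 1 on the others. The same 2 variable-region genes were high on arrays of 2 different lymphomas. On ADR 5 d of 4936, big 5043 and small 5043, Igkv8-30 lay 4.71, 4.63 and 4.07 above the lymphoma median. Igkv14-111 lay 4.23, 3.61 and 3.66 above it. Another clone within each tumour would give this picture only if both clones used these same genes. The genes were chosen after their values were seen, and another clone was not tested.

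Fibroblast markers were higher in big than in small cells, 15 of 16 of them in all 3 lymphomas. Fibroblasts carried over into the big fraction may account for this, and stay open because the test could have excluded them only with fewer than 8 such members. Of 25 fibroblast markers with a probe set, 16 passed the filter, which 3 high arrays such as the big ones suffice to meet. The filter may thus favour members that are higher in big cells. The sort for morphologically big cells is not known to remove fibroblasts. A difference between big and small lymphoma cells stays open too, as the B cell list median of -0.10 leaves room for a small share of other cells. Among abundant fibroblast genes, Fn1 had 3.94 and Bgn had 3.54 in this comparison, and Tagln had -0.05, 0.06 and -0.33 in lymphomas 4146, 4936 and 5043. Xist was 1.81, 3.10 and 0.19 higher and the Y-linked gene Eif2s3y 1.09, 3.08 and 0.21 higher in the big cells, and these genes were chosen after their values were seen.

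The lysozyme genes Lyz1 and Lyz2 were far higher after 5 days of ADR with 4-OHT than in untreated cells. Macrophages that outlive the lymphoma cells in culture may account for this, since the median of the rest of the macrophage list was 1.52, and the test could have excluded them at 0 or less. Of 28 macrophage markers with a probe set, 17 passed the filter, which 3 high arrays suffice to meet, so the filter may favour a higher median. Expression of lysozyme by the lymphoma cells stays open and was not tested separately, and no sort is named for these cultures.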

How the results depend on the processing

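The fits without 3 or 4 arrays with outlying values, with array weights and without each single array were chosen after the data were seen. A fit of all 18 arrays was foreseen and not run, because the 18th holds no values.

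Leaving out the lymphoma block (no replicate block, so that arrays were compared without their pairing) raised the counts from 350 to 623 for ADR+4-OHT 5 d against untreated (348 shared) and from 478 to 920 for big outgrowth against ADR+4-OHT 5 d (474 shared). It raised those of 0 to 13 for ADR+4-OHT against ADR at 5 days, 1 for ADR 5 d against untreated, 30 for big against small, 1 for small outgrowth against untreated and 1 for the interaction. By construction the block costs degrees of freedom while the lymphoma medians were equal already; whether this is the whole cause was not tested.

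The mean over a gene's probe sets gave 1 for ADR+4-OHT against ADR at 5 days and 212 for ADR+4-OHT 5 d against untreated. Every probe set on its own gave 1 for the former and 66 for big against small. The compared arrays alone gave 0 for ADR+4-OHT 5 d against untreated and 0 for big outgrowth against ADR+4-OHT 5 d, with fewer arrays for the variance, and the gene-by-gene paired test gave 0 and 4 for these and 1 for ADR outgrowth against untreated. Array weights gave 523, 10, 1304, 61 and 1992 for ADR+4-OHT against ADR at 5 days, ADR 5 d against untreated, ADR+4-OHT 5 d against untreated, big against small, and big outgrowth against ADR+4-OHT 5 d. Without the 3 arrays the counts were 3 for big against small and 46 for big outgrowth against ADR+4-OHT 5 d, and without 4 they were 2, 42 and, for ADR+4-OHT 5 d against untreated, 793. With an estimated correlation 0 of 76 list shifts passed. The cause was not tested unless stated.

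Leaving out a lymphoma or a single array gave counts from 0 to 19 for ADR+4-OHT against ADR at 5 days, 0 to 3 for ADR 5 d against untreated, 0 to 545 for ADR+4-OHT 5 d against untreated, 0 to 25 for big against small, 0 to 1 for small outgrowth against ADR outgrowth, 0 to 804 for big outgrowth against ADR+4-OHT 5 d and 0 to 2 for the interaction. The list shifts passing ranged from 73 to 94 and the correlation of fold changes from -0.10 to 0.30. Where leaving out a lymphoma leaves 1 ADR outgrowth array, that array is assumed to vary like the other groups.

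Some list medians reversed, and the cause was not tested. Over the fits without a lymphoma, glycolysis for ADR+4-OHT against ADR at 5 days ran from -0.053 (without 4936) to 0.473 and lysosome for small outgrowth against ADR outgrowth from -0.177 (without 4936) to 0.54. Interferon ran from -1.37 to 0.223 (without 4146) for small outgrowth against ADR outgrowth, from -0.089 (without 4146) to 1.16 for ADR outgrowth against untreated and from -1.95 to 0.094 (without 4146) for the interaction, and NF-kB from -1.14 to 0.61 (without 4146) for the interaction. Of the 76 list shifts, 74 kept direction and threshold without the block, 73 without a filter, 73 with the mean over probe sets, 75 with quantile values, 73 with array weights, 68 without 3 arrays and 67 without 4, and 64, 62 and 64 without lymphoma 4146, 4936 and 5043. Of the 54 named results past the threshold, 52 kept it without the block, 46 without a filter, 40 with the mean over probe sets, 50 with quantile values, 54 with array weights, 36 without 3 arrays and 32 without 4; without lymphoma 4146, 4936 or 5043, 52, 41 and 52 lost the threshold and kept their direction.

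The counts for ADR+4-OHT 5 d against untreated and for big outgrowth against ADR+4-OHT 5 d stayed within 1.5 times of 350 and 478 with no filter, the stricter filter, quantile values, median centring and the variance trend, at 304 to 395 and 392 to 480.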

Other observations

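The 6 tests of array groupings at the end of this part were planned, as were the lists, and the fits without 3 arrays were chosen after the results were seen.

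The small outgrowth cells after ADR with 4-OHT, compared with untreated cells, had lower levels of replication, repair and glycolysis genes and higher levels of unfolded protein and stress response genes. The small cells were sorted by size and the labels name no sort for the untreated cells, so this comparison does not separate treatment and outgrowth from the sort. The difference between 3′ and 5′ Actb control probe sets was higher in the small cells by 0.140, 0.156 and 0.003 in lymphomas 4146, 4936 and 5043. Gapdh and Tfrc did not move the same way in all 3. Replication genes had a median of -0.60 with 0 of 41 passing over all genes or the list alone, and the medians in lymphomas 4146, 4936 and 5043 were -0.41, -0.84 and -0.53. Of 22 repair genes 2 fell over the list alone (median -0.51), and of 18 glycolysis genes 5 fell (median -0.50). Of 26 unfolded protein and stress response genes 7 rose over the list alone (median 0.42). The fibroblast (0.52), lysosome (0.33), plasma cell (0.44) and Wnt (0.18) lists were called up and the mitosis (-0.18) and heterochromatin (-0.21) lists down, which makes 10 calls, and the adjusted p lay between 0.445 and 0.875 with an estimated correlation. The stress call ended without lymphoma 5043 (adjusted p = 0.644) or the 3 arrays that stood apart (0.422), and the mitosis call without 4936 (0.67). The limma count over all genes was 0, 987 had an unadjusted p under 0.05, the gene-by-gene paired test called 0 and 1 passed without the block.

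The outgrowth after ADR alone, compared with untreated cells in lymphomas 4146 and 4936, had higher levels of interferon genes and lower levels of B cell genes, in lymphoma 4146. The differences between 3′ and 5′ control probe sets of Gapdh and Actb, signs of RNA quality, were lower in the outgrowth in both. The interferon medians were 1.83 in 4146 and -0.01 in 4936, and the B cell medians -1.11 and -0.15. Over both, the interferon list had 0.54 with 0 of 35 passing, the B cell list -0.45 with 2 of 25 falling over the list alone, the macrophage list 0.70 and the mitosis list -0.16, each with none passing. These were the 4 lists called, and the adjusted p lay between 0.5 and 0.875 with an estimated correlation. Without lymphoma 4146 the interferon median was -0.09 and the B cell and macrophage calls ended (adjusted p = 0.654 and 0.662), and the mitosis call ended without 4936 (0.273), 5043 (0.318), the block (0.216) or the filter (0.119), or with the mean over probe sets (0.0563). Of all genes 0 passed in limma, 534 had an unadjusted p under 0.05 and the gene-by-gene paired test called 1.

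The 6 arrays of each comparison of 3 with 3 can be split in 10 ways, which is too few for a share under 0.05. The number of splits with a result as large, the real one included, was 1 for ADR+4-OHT 5 d against untreated, with 350 genes in the real split and 0 as the highest of the others. It was 1 for big outgrowth against ADR+4-OHT 5 d, with 478 and 0. It was 10 for ADR+4-OHT against ADR at 5 days (0 and 0), big against small (0 and 0), small outgrowth against untreated (0 and 0) and ADR 5 d against untreated (0 and 5). Of the 10 splits, 4 part all 3 pairs of the same lymphoma as the real split does, and the highest other count among those was 0 in every comparison; the others keep both arrays of a lymphoma on 1 side.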
